A study of Drosophila melanogaster with 4 samples.

How the data were processed

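Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on Drosophila melanogaster embryos with the rabbit polyclonal antibody RF13, raised against the C-terminal part of the Paired protein (Prd). Embryos came from a 0 to 12 h egg collection of the y; cn bw sp strain and were fixed in 1.8% formaldehyde for 15 min, per the labels' protocols. Of the 4 samples, 2 were Prd ChIP libraries and 2 were input DNA libraries. The labels number the replicates of each group but do not say whether they came from separate embryo collections.

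The data consist of 1 peak list for the whole series. Each peak has a chromosome arm or scaffold, a start, an end and 1 score, on FlyBase release 5, per the file headers. The source field of the deposited list names MACS, a program that finds regions with more ChIP reads than a background model predicts. The submitters' processing notes name CASAVA (versions 1.7.0.2 and 1.7.0.3), BWA, MACS2 and the genome build BDGP5, without saying what each was used for. The threshold for a peak, the way both replicates were combined, the scale of the score and the read depth of each library are not given in the sources used here. The deposited score was therefore used only within this list, to describe, rank, filter and compare its peaks, and differences and ranges of the score are on that unstated scale. The peaks were numbered without a gap, and no neighbouring peaks overlapped. The list carries no value per sample, so no error between replicates could be attached to any peak. Which of the libraries entered the peak calls, and how input was used in them, is not given in the sources used here. Depth is unknown, and no limit on missed peaks was set.

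Before the data were examined, 7 tests were fixed, of which 2 were made. Counting peaks per arm was planned only with arm lengths from a release 5 genome. It was made here with spans taken from the list, a departure from the plan. The tests of annotation class, gene lists, sequence motifs, score by motif and score by promoter position need a genome or annotation of release 5, which was not used here. The gene name table at hand belongs to release 6, and coordinates were not carried between releases, so peaks are given by position and not by gene. The rule for naming items, also fixed beforehand, was then the 10 highest-scoring peaks by position. The dense region of 2L is the group with the most peaks when peaks are chained with gaps of at most 50 kb. Other regions are named where at least 4 peaks chained with gaps of at most 10 kb. Both gaps were chosen after the list was seen. Any other region or arm named below was chosen after its values were seen.

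The number of peaks on each of the 6 placed arms (2L, 2R, 3L, 3R, 4 and X) was compared with the arm's share of the summed spans by a two-sided exact binomial test, adjusted over the arms by the Benjamini-Hochberg method. The span from the first to the last peak stood for the arm's length, a choice made after the list was seen, and on arm 4 that span rests on 5 peaks. Such a span cannot exceed the arm's length and tends to fall further short where peaks are sparse. Peaks per Mb on X may therefore be overstated relative to the autosomal arms. The comparison of X with the autosomal arms by score used the same test, adjusted over 8 score thresholds. Intervals are 95% Clopper-Pearson intervals. These intervals and the exact binomial p-values treat peaks as independent, and they do not cover differences in mappability or between samples. The nearest-neighbour test counted peaks whose midpoint lay within 10 kb of another midpoint. It compared that count with 10000 random placements of the same peak widths on the same arms without overlap, one-sided. Median scores and widths were compared by two-sided permutation tests with 100000 resamples, adjusted over the 10 comparisons made. These permutations shuffled single peaks and so also treat peaks as independent. Windows of 1 Mb were also permuted, with the densest region of 2L left out, so that neighbouring peaks stayed together. The repeat distance within a region was the lag between 2 and 10 kb, in bins of 10 bp, with the highest autocorrelation of peak coverage, against 10000 random placements within the region.

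The alternatives tried were peaks above the median score, peaks within 1 kb merged, neighbour distances of 5 and 50 kb, the 5 long arms without arm 4, and leaving out the densest region of 2L or the unplaced sequences. A merged peak took the highest score among its pieces. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9. Tests of neighbours, medians, repeats, the X count, windows and stretches without a peak were tested on simulated data. Fisher's test, the correlation and the other arms' counts were not. In 50 simulated lists of 944 peaks, the nearest-neighbour test called 4% of random lists and 100% of lists with 20% of the peaks moved next to another. With 944 simulated scores, the median test called 2% of lists without a shift and 100% with a shift of 5. The repeat test called 5% of 20 regions of 80 random peaks, and found the planted period of 5000 bp in 75% of 20 regions of 74 peaks. In 50 lists of 939 peaks, the exact binomial test of X called 2% of random lists and the permutation of windows 6%, and both called 100% of lists with 60% of the X peaks kept. The longest stretch of 99 X peaks was called in 4% of 50 random lists and in 100% with a stretch of 2.5 Mb emptied. The lists for X, windows and the longest stretch placed peaks independently, without the closeness of neighbours in the real list. The simulated scores of the median test were likewise shuffled singly. The rates of false calls of all these tests therefore do not cover peaks that lie close together.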

Results

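Binding of Paired (Prd), a pair-rule transcription factor with a paired domain and a homeodomain that acts in segmentation of the embryo, was mapped across the genome of 0 to 12 h Drosophila melanogaster embryos. The series holds ChIP DNA (2 samples), input DNA (2 samples) and 1 list of 1155 peaks. The embryos were of the y; cn bw sp strain, from which the reference genome of the species was sequenced. Peaks covered 516578 bp and had a median width of 341 bp (interquartile range 250 to 548 bp, full range 201 to 2149 bp). The authors' peak score had a median of 13.9 and ran from 6.19 to 228. Wider peaks had higher scores (Spearman's rho = 0.74 across 1155 peaks, permutation p = 0.0001, the smallest that 10000 resamples give). Width and score come from the same peak calls, so this test cannot separate a property of the peaks from the calling. Peaks are not independent replicates. Read depth per library and values per replicate were not used here, so no peak carries an error of its own.

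The highest-scoring peaks were spread over all long arms. The first lay on 3L at 22401011 to 22401592 (score 228), towards the high-coordinate end of the arm. The next was on 3R at 304797 to 305509 (score 219), towards the low-coordinate end of its arm. The third was on 3L at 698879 to 699908 (score 209). On X, the peak at 17401091 to 17401762 had a score of 206. The fifth was on 3R at 10919492 to 10920498 (score 203), and the sixth on 2L at 11808081 to 11808949 (score 176). Ranks 7 to 10 were a 2R peak at 16723444 to 16724039 (score 137), a 3R peak at 15715742 to 15716480 (score 135), a 3L peak at 20776598 to 20778435 (score 128) and a 2R peak at 7284888 to 7285481 (score 119). The 3L peak of rank 9 was 1838 bp wide, and the other 9 were between 582 and 1030 bp wide. All positions are on FlyBase release 5. A score of 50 or more was reached by 70 peaks, all of them on 2L, 2R, 3L, 3R or X.

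The arms differed in how many peaks they carried. X had 99 peaks, 0.58 times the 171 that its span predicts (95% CI 0.48 to 0.70, exact binomial test, adjusted p = 8.25e-10). 2L had 264 peaks, 1.41 times its prediction (95% CI 1.27 to 1.56, exact binomial test, adjusted p = 6.63e-09). The counts on 2R (179 peaks), 3L (175), 3R (222) and arm 4 (5) lay between 0.92 and 1.09 times their predictions and did not pass the exact test (adjusted p from 0.359 to 1.0). The surplus on 2L came from a single region: without it 2L had 180 peaks, 1.05 times its prediction (exact binomial test, adjusted p = 0.662), and X still lay at 0.64 times (adjusted p = 9.32e-07). Without that region 2R, at 1.19 times its prediction, passed the exact test (adjusted p = 0.0313). Predictions share the total over all arms, so the low count on X raises the ratios of the others. Without the region, 2R had 8.91 peaks per Mb against 8.07 on 2L, 2R, 3L and 3R together, a difference that was not tested. The exact test treats peaks as independent, while many lay close together, and only X was also compared in windows. Among peaks above the median score, X had 64 against 75.1 predicted and did not pass (exact binomial test, adjusted p = 0.36), while 3L lay at 0.73 times its prediction (adjusted p = 0.0172). With the dense region also left out of the peaks above the median score, no arm passed the exact test: 3L lay at 0.85 times its prediction (adjusted p = 0.443), 2R at 1.07 times (adjusted p = 0.798) and X at 0.99 times (adjusted p = 0.945).

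**Figure D1:**
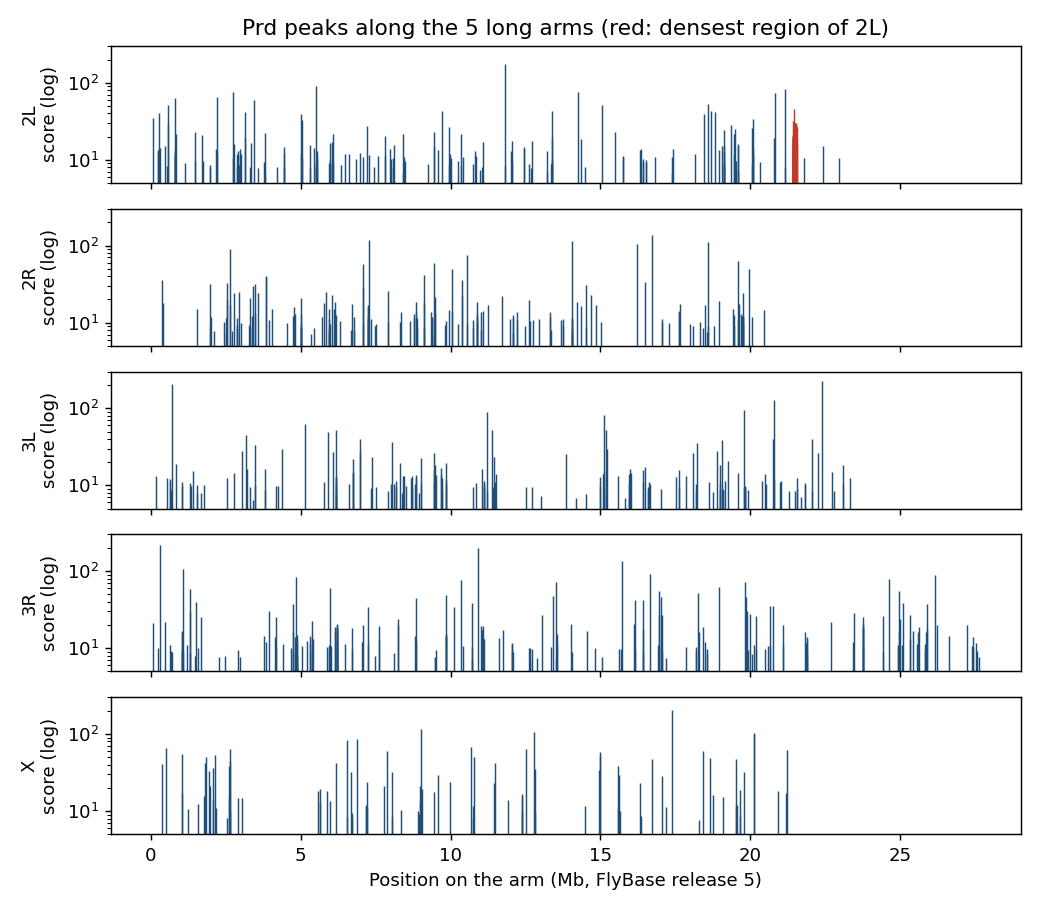
Each line is a Prd peak at its position on one of the 5 long arms (x axis, Mb on FlyBase release 5), drawn up to its score (y axis, log scale). The 84 peaks of the densest region of 2L are red and reach at most 45.8, while the highest scores on each arm lie elsewhere.

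The region that set 2L apart, found by chaining peaks with gaps of at most 50 kb, lay at 21416997 to 21543149, near the high-coordinate end of the arm. It held 84 peaks within 126153 bp, which is 31.8% of the 2L peaks in 0.55% of the 2L span. Peaks covered 45.3% of the region. Their median score was 16.4 against 12.4 for the 860 other arm peaks (permutation test, adjusted p = 0.000967), and their median width was 492 bp against 322 bp (permutation test, adjusted p = 5e-05). None of the 84 reached a score of 50, against 70 of 860 elsewhere on the arms (Fisher's exact test, two-sided, p = 0.00178). A share of up to 3.57% is allowed by 0 of 84, for counting error only. The permutation tests, Fisher's test and this limit treat the 84 peaks as independent. If the peaks are copies of a few sites in a repeat, these values overstate the evidence. The peaks recurred at a fixed distance: the autocorrelation of peak coverage was highest at 5070 bp, with a value of 0.46. The highest value in any of 10000 random placements was 0.25 (permutation p = 0.0001, the smallest they can give). The 22 peaks of at least 900 bp in the region were a median of 5060 bp apart (interquartile range 4717 to 5238 bp). A stretch of 11615 bp from 21439395 to 21451009 had no peak.

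**Figure D2:**
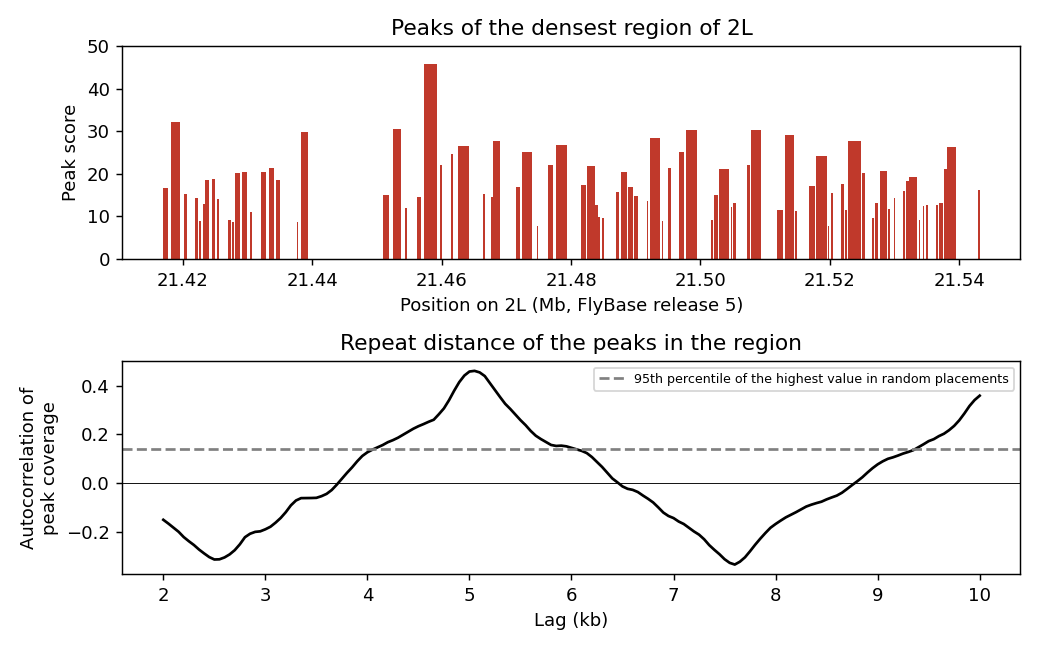
Top: the 84 peaks of the 2L region (x axis, Mb on FlyBase release 5), each bar as wide as its peak and as high as its score. Bottom: autocorrelation of peak coverage (y axis) against lag in kb (x axis), highest at 5070 bp and above the dashed 95th percentile of random placements (0.14).

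Peaks lay closer together than random placement gives, where placement was uniform over each arm's span and took no account of mappability. Of 944 peaks on the placed arms, 467 (49.5%) were within 10 kb of another, against 15.3% on average in 10000 random placements (95% of placements from 12.3% to 18.3%, permutation p = 0.0001, the smallest they can give). The share was 46.4% on 2R, 46.8% on 3R, 40.4% on X and 46.7% on 2L without its dense region, with 70 of 175 peaks on 3L, and each arm passed the same permutation test (p = 0.0001). Without the dense 2L region and with peaks within 1 kb merged, 27.4% were near another, against 11.8% at random (permutation p = 0.0001). Chaining these 944 peaks with gaps of at most 10 kb, measured between peak edges, gave 630 groups, of which 466 were single peaks and 15 held 4 or more. At that gap the dense 2L region counts as a group of 65 and a group of 19 peaks. Peaks that had a neighbour within 10 kb had a median score of 12.2 against 13.0 for the others, a difference that did not pass the permutation test (adjusted p = 0.305, dense 2L region left out).

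Outside the 2L region, the groups of 4 or more peaks were on 2L, 2R, 3L and 3R. A group of 7 on 3R at 6207113 to 6213825 had peaks over 67.7% of its 6713 bp, with scores from 9.44 to 20.9. On 3R at 25583394 to 25599229 there were 6 peaks, with scores from 8.11 to 16.2. Groups of 5 lay on 2L at 815291 to 821125 (highest score 63.2), on 3L at 6174644 to 6181172 (highest 52.3), on 2R at 14040833 to 14049563 (highest 115), on 2L at 13366048 to 13379013 (highest 43.0) and on 2R at 7247005 to 7258383 (highest 16.9). Among the groups of 4, the one on 2L at 5519120 to 5524466 held the highest score, 89.98, next to peaks with a group median of 8.62. The group on 3R at 23744480 to 23748487 had peaks over 84.4% of its 4008 bp and scores from 10.3 to 20.9. The other groups of 4 were on 2L at 19122909 to 19133773, on 3R at 4880880 to 4891258, on 2R at 5939254 to 5954518 and on 3R at 9837210 to 9858458, with highest scores of 24.5, 14.9, 15.2 and 49.6.

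X carried fewer peaks than the autosomal arms, but higher-scoring ones. The median score was 18.7 over 99 X peaks and 12.6 over 840 peaks on 2L, 2R, 3L and 3R (permutation test, adjusted p = 2.5e-05). The permutation of medians treats peaks as independent, while 40.4% of X peaks lay within 10 kb of another, so its p-values may overstate the evidence. Without the dense 2L region the autosomal median was 12.0, and X peaks were also wider (median 452 bp against 317 bp, permutation test, adjusted p = 5.71e-05). Width and score rose together on the placed arms without that region (Spearman's rho = 0.75), so the greater width is not a separate result. In peaks per Mb of span, with that region left out, X lay at 0.59 times the autosomal arms over all scores (95% CI 0.47 to 0.73). It lay at 1.21 times for scores of 20 or more (95% CI 0.86 to 1.68). For scores of 30 or more there were 37 peaks on X and 99 on the autosomal arms, 1.68 times as many per Mb on X (95% CI 1.12 to 2.47, exact binomial test, adjusted p = 0.0243). For scores of 50 or more the counts were 20 and 50, a ratio of 1.80 (95% CI 1.01 to 3.08, exact binomial test, adjusted p = 0.0477). The lower limit of 1.01 leaves little room for spans that may overstate the density on X. At 100 or more the counts were 5 and 13, a ratio of 1.73 that did not pass (95% CI 0.48 to 5.17, exact binomial test, adjusted p = 0.403). In 1-Mb windows, with the dense 2L region left out, X had 4.80 ± 3.02 peaks (SD, 20 windows). The autosomal arms had 8.10 ± 4.15 (SD, 92 windows), a difference that passed the permutation of windows (adjusted p = 0.00303). Peaks with a score of 30 or more numbered 1.80 ± 1.44 per X window and 1.08 ± 1.10 per autosomal window (permutation of windows, adjusted p = 0.0243). With that region left out, dropping each autosomal arm in turn gave ratios from 1.57 to 1.83 at a score of 30 or more (exact binomial test, unadjusted p from 0.00479 to 0.0273). The X comparisons by score were chosen after the list was seen.

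**Figure D3:**
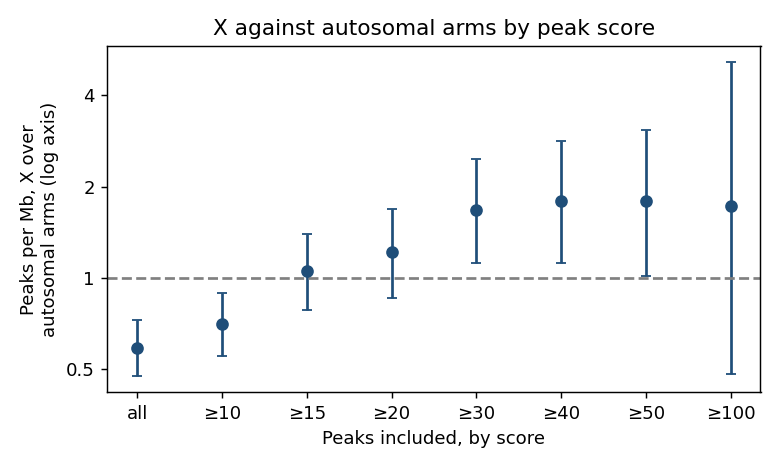
Peaks per Mb on X divided by peaks per Mb on 2L, 2R, 3L and 3R (y axis, log scale) for peaks at or above each score (x axis), with the dense 2L region left out and 95% intervals as bars. The ratio is 0.59 over all peaks and 1.68 for scores of 30 or more, with the dashed line at equal density.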

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

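All tests of the unplaced sequences were chosen after the list was seen. Sequences other than the 6 placed arm sequences held 211 peaks, 18.3% of the list, and were left out of the comparisons between arms. Of these, 197 lay on Uextra, a release 5 collection of sequence outside the placed arms. Another 13 lay on 4 heterochromatic scaffolds (2LHet, 2RHet, 3LHet and 3RHet) and 1 on U. The assembly quality of these sequences was not examined. The 211 peaks are listed here because they are signal in sequence that no comparison between arms used. They still count in the list's totals, medians and correlation of width with score.

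Uextra peaks had a median score of 19.5 against 12.4 on the arms outside the dense 2L region (permutation test, adjusted p = 2.5e-05) and a median width of 412 bp against 322 bp (adjusted p = 6.25e-05). None of the 197 reached a score of 50, against 70 of 860 on the arms (Fisher's exact test, p = 5.69e-07). By the same approximate limit as for the dense 2L region, 0 of 197 allows a share of up to 1.52%. The tests and this limit treat the 197 peaks as independent, which peaks in multi-copy sequence would not be. Multi-copy sequence that gathers reads is a candidate explanation and stays open: the interquartile range of Uextra scores was 0.88 times that of the arms, which does not decide, and neither the sequence nor the reads were used here. Prd binding in unplaced DNA, the biological explanation, was not tested.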

How the results depend on the processing

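Of 53 alternatives, 34 kept direction and side of the threshold (or, with no test, moved by under 1.5 times), and 10 crossed the prediction, of which 9 passed in neither setting. Keeping peaks above the median score left 573 peaks by construction (and moved their median width and score), brought 3L to 0.73 times its prediction (past the threshold) and X to 0.85 (no longer past it). 2R turned to 0.93, 3R to 1.02, and arm 4 went to 0.43, none past. Leaving out the dense 2L region, chosen after seeing the data, brought 2L to 1.05 (no longer past) and 2R to 1.19 (past), and turned 3L to 1.01, 3R to 1.08 and arm 4 to 1.03, not past. Merging peaks within 1 kb, not planned for the arm counts, brought 2L to 1.17 (no longer past) and turned 3L to 1.00, 3R to 1.03 and arm 4 to 1.16, not past. Both choices together, high scores and no dense region, also not planned, brought X to 0.99 (no longer past) and turned 2L to 0.91 and 3R to 1.18, not past, with arm 4 at 0.50. In that setting 3L (0.85, adjusted p = 0.443, exact binomial test) and 2R (1.07, adjusted p = 0.798) did not pass either. The 2L shifts to 1.05 and 1.17 follow from removing or joining the region's peaks. The turn of 2L to 0.91 took both choices, with 1.05 without the region alone and 1.47 above the median score alone. Without the region, the shifts of 2R, 3L, 3R and arm 4 follow from its construction, as each kept its peaks while its prediction dropped with the total (2R kept 179 peaks, with its prediction going from 165 to 150.1). On merging, arm 4 likewise kept its 5 peaks, and 3L and 3R lost smaller shares of their peaks than the arms together. For the shifts of X, 2R, 3R and arm 4 among peaks above the median score the cause was not tested, and for 3L the call rests on the region's peaks in the total. The share of peaks near another peak passed in every setting, at 1.31 to 5.24 times random. No paired analysis was possible because the peak list holds no value per replicate. For the same reason no replicate could be left out. The summit alternative and those for annotation, gene lists, motifs and scores by motif or position were not run, as no summit is listed and no release 5 genome was used. Depth is unknown, so what the list can miss is unknown.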

Other observations

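All tests in this part were chosen after the list was seen. The longest stretch of X without a peak ran from 3056985 to 5592171, 2.54 Mb, against 1.07 Mb on average for the longest stretch in random placements of the 99 X peaks (permutation p = 0.0007, adjusted p = 0.0035 over 5 arms). With peaks within 10 kb placed as 1 group the adjusted p was 0.024 (permutation test). Placement was uniform here too and took no account of mappability. On 2R the longest stretch, 15022369 to 16207096 (1.18 Mb), passed with single peaks (permutation test, adjusted p = 0.0065) and not with groups (adjusted p = 0.116). The longest stretches of 2L, 3L and 3R, from 0.86 to 1.01 Mb, did not pass (adjusted p from 0.118 to 0.167).

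The dense region of 2L recurred with a period of 5070 bp, far above random placements of its own peaks, which is consistent with a tandem repeat of one sequence unit. Textbook knowledge places the replication-dependent histone genes in such an array on 2L, so the histone gene repeats are a candidate source. The region length divided by the period is 24.9 units if the repeat also fills the stretch without a peak, and 22.6 units without that stretch. The release 6 gene table lists 23 His1, 23 His2B, 23 His3, 22 His4 and 20 His2A genes in a single run of neighbours on 2L. The unit count does not exclude that source, and its position was not compared because the releases differ. Whether each unit holds Prd-bound DNA, or a near-identical sequence gathers reads from many copies, remains untested without the reads.

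X had fewer peaks than the autosomal arms and higher-scoring ones. The dense 2L region does not account for the lower number, since X stayed at 0.59 times the autosomal density without it. Merging peaks within 1 kb did not remove the score difference: the X median was still 8.04 higher, with the dense 2L region kept in. A merged peak took the highest score of its pieces, which need not be the score of an unsplit peak. Splitting of autosomal peaks is therefore not excluded. If fewer X copies than autosome copies, as in a collection of both sexes, lowered X at every score, X would not exceed the autosomal arms. At scores of 30 or more X had 1.68 times the autosomal density. Whether fewer copies act that way depends on the score scale and the use of input, which are not known. This prediction was also written after the X pattern was seen, so the comparison does not decide. Fewer copies may contribute to the loss of low-scoring X peaks, and a property of X chromatin or of Prd sites on X stays open and untested.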
